A study of Mus musculus with 9 samples.

How the data were processed

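RNA of single NIH3T3-CG cells was measured in 9 libraries made with the 3' gene expression kit of 10x Genomics, which carries unique molecular identifiers (UMIs). Per the submitters' processing notes, reads were processed with Cell Ranger against the mouse build mm10. Per the file headers, the matrices of Experiment 1 were written by software version 3.1.0 with 31054 features and those of Experiment 2 by version 6.0.1 with 32286 features, each including an added feature named GFP_g1. The deposited values are UMI counts per gene and barcode, without normalization, as the authors' pipeline wrote them, and every value was checked to be a whole number. The filter behind the list of barcodes is not stated. Gene positions are those of GENCODE vM21 on GRCm38 (mm10). Whether the counting used the strand is not given, so counts of genes annotated antisense to another gene (Snhg9, B930036N10Rik), of near-identical families (the histone genes, Klra4, Ctla2b, Saa3 and ribosomal protein genes) and of the ribosomal RNA-like AY036118 are less certain.

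Libraries were grouped by SAG time and Dox from the labels, with 17 h and 19 h taken as the same time point. The labels give experiment numbers and not whether cultures were separate, so the p-values measure only the spread between these libraries, which may be technical. Features were joined by gene ID, 30407 of them shared (597 with a changed symbol); features outside the shared set held 0.071% to 0.858% of the UMIs of a library. Cells with at least 5000 UMIs and at most 10% mitochondrial UMIs were kept and their counts were summed per library, to between 19422658 and 106128757 UMIs. The mitochondrial limit removed 25.9% to 46.3% of the barcodes with at least 5000 UMIs.

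Genes were tested with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood F test, adjusted p under 0.05 by Benjamini and Hochberg) in R 4.3.3. The SAG comparisons and the difference of the SAG response with Dox used all 9 libraries, with condition and experiment as terms and 2 residual degrees of freedom; without the experiment as a block edgeR called 0 genes at 30 h, with 85 at unadjusted p under 0.05 and 12 called by DESeq2 with the block. The conditions with Dox have 1 library each and are assumed to vary as the others do. The Dox comparison used the 6 libraries of Experiment 2 with SAG time as a term, also with 2 residual degrees of freedom. Standard errors of log2 changes are the change divided by the square root of F. The changes given within an experiment are differences of log2 CPM with a prior count of 2, and the medians of a list within an experiment or time are of these differences and were not tested. DESeq2 1.42.0 (Wald test, same terms) was the other tool.

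Of 24 lists of genes written from general knowledge, the genes called were counted over all genes tested and adjusted over the list alone. Lists were tested against the other genes with camera of limma 3.58.1 (preset correlation 0.01), and again with an estimated correlation. The estimated form rests on the 2 residual degrees of freedom, which leaves it little power. A list that fails there is not thereby shown to owe its result to correlation between genes. With fry the genes of a list were tested against no change, on balance to 1 side or in either direction, and not against other genes. The p-values were adjusted over the 24 lists of a comparison. The comparisons, lists, cell filters, depth and the rule for naming genes were fixed before the data were examined. Among those the rule names in every case are Gli1, Ptch1, Hhip, Gli2, Gli3, Smo, Sufu and any added feature. For 30 h of SAG and for Dox it adds the 8 called genes with the largest rise and the 8 with the largest fall that reach 10 CPM in a group compared and move the same way in both experiments or at all 3 times. For 17 to 19 h, and from there to 30 h, it adds 4 in each direction, or where none qualify the 4 of smallest p in each direction with values only. It also adds the called genes of the Dox difference, up to 4 genes per list by p, and across cells the 8 highest and 4 lowest correlations with Gli1. Some genes that the rule names are not reported here.

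For values per cell, kept cells with at least 10000 UMIs were thinned at random to 10000 UMIs with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, levels of single libraries 95% Poisson intervals and a count of 0 an upper limit of 3 counts. The excess variance is the variance less the mean, divided by the squared mean, with an interval from 1000 resamplings of cells. Correlations with Gli1 were Pearson's r of log counts in each of the 6 SAG-treated libraries, tested over libraries with an exact sign-flip permutation test, and 7519 genes with a mean of at least 0.05 UMIs per thinned cell were ranked by the median r. Lists were set against 10000 random lists of genes of like mean. Doublet scores came from scrublet in scanpy 1.11.5. It called 0.02% of cells in Experiment 2 at 19 h without Dox, where it did not work, and 0.34% to 4.03% elsewhere. In a single line a doublet of alike cells can look like a single cell. Leaving out its calls is thus a weak check in each library.

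The gene tests were tested on simulated data of the same depth, with 100 genes changed 1.5-fold and 100 changed 3-fold. Genes were drawn independently, with the spread usual for their level and no difference between the experiments. The shares found and the false calls below therefore hold for such data and may be too favourable for these libraries. At 30 h of SAG the test found 7% of 1.5-fold and 99% of 3-fold changes, with 4 false calls among 14354 genes. For Dox it found 86% and 100%, with 5 false calls among 13645 genes. The alternatives concerned the cell filters, doublets, normalization, gene filter, depth, model and single libraries. Clustering into cell types was left out, since the cells are a single line, and expression was not scored per cell.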

Results

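The series measured the RNA of single cells of NIH3T3-CG, a line of mouse embryonic fibroblasts, during treatment with SAG, a small molecule that switches on the Hedgehog pathway by activating Smoothened. Cells were released with trypsin, and droplets of the 10x Genomics system tagged the 3' end of each captured transcript with a cell barcode and a unique molecular identifier (UMI), so that each UMI counts 1 captured molecule. Experiment 1 was sampled at 0, 17 and 30 h of SAG, and Experiment 2 at 0, 19 and 30 h, both without and with Dox. The labels do not say what Dox induces in these cells. They do not mention Dox for Experiment 1, which was taken as without it. The 9 libraries thus made 6 conditions. Without Dox these were 0 h, 17 to 19 h and 30 h, with 2 libraries each (1 per experiment). The same times with Dox had 1 library each. No library is labelled as kept without SAG for the later times. A change with SAG time is therefore not separated from a change with time in culture or with harvest.

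The deposited matrices of Experiment 1 held 38743296, 33787321 and 35950402 UMIs at 0, 17 and 30 h. Those of Experiment 2 held 152207128, 198610010 and 141259840 UMIs without Dox and 72645052, 130652566 and 136808770 with Dox, at 0, 19 and 30 h. Cells with at least 5000 UMIs and at most 10% mitochondrial UMIs were kept. They numbered 933, 571 and 585 in Experiment 1, 2979, 6520 and 2159 in Experiment 2 without Dox, and 1362, 2046 and 1578 with Dox. The median kept cell had 29327, 33279 and 40905 UMIs in Experiment 1, 28335, 8025 and 48188 in Experiment 2 without Dox, and 29144, 38969 and 45291 with Dox. The shallow library, Experiment 2 at 19 h without Dox, held 24730 barcodes with a median of 4062 UMIs and none below 2052, and 60% of its kept cells had between 5000 and 10000 UMIs. Kept cells with under 1% mitochondrial UMIs made up 19.7% of Experiment 2 at 30 h without Dox, 18.2% at 19 h with Dox and 17.9% at 30 h with Dox, against 0.4% to 1.4% in the other 6 libraries.

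The cells were fibroblasts throughout. Col1a2, a chain of type I collagen, and Fn1, fibronectin, were at 822 to 2527 and 1297 to 3009 CPM (UMI counts scaled to library size). Cells with UMIs of at least 3 of the 9 fibroblast markers made up 91.95% to 99.64% of each library at a fixed depth. Cells with at least 3 smooth muscle or myofibroblast markers made up 0.37% to 9.29%, the highest share in the library at 30 h with Dox, and the 8 other marker classes gave 0 such cells. Hhip, which encodes a Hedgehog-binding membrane protein and is a pathway target in many tissues, had 0 UMIs in all 9 libraries, which allows up to 0.0293 to 0.138 CPM per library.

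At 30 h of SAG without Dox, the main readout of the pathway was switched on. Gli1 (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974), which encodes a zinc finger transcription factor and is the classical target of the pathway, rose by 6.46 on the log2 scale (SE 0.53, adjusted p = 3.71e-09, edgeR, n = 2 libraries per time). It went from 0.205 CPM (7 UMIs) to 3.97 CPM in Experiment 1 and from 0.0498 CPM (3 UMIs) to 17.1 CPM in Experiment 2, ratios of 19.3 (95% counting interval 9.06 to 49.3) and 344 (118 to 1670). Ptch1 (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598), the receptor for Hedgehog ligands and the pathway's own brake, rose by 2.60 (SE 0.40, adjusted p = 0.000558), by 0.93 within Experiment 1 and 4.02 within Experiment 2. Counts of the added GFP_g1 feature rose by 2.83 (SE 0.33, adjusted p = 8.26e-06), by 1.62 and 3.53 within the experiments. The labels do not describe the sequence behind this feature. Gli2, the main activating factor of the pathway before Gli1 is made, was not called, at 0.79 (SE 0.28, adjusted p = 0.254), with 0.17 in Experiment 1 and 1.31 in Experiment 2. Nor were Gli3 at -0.42 (SE 0.24, adjusted p = 0.572), Smo at 0.20 (SE 0.24, adjusted p = 0.821) and Sufu, an inhibitor of the GLI proteins, at 0.63 (SE 0.26, adjusted p = 0.386).

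**Figure D1:**
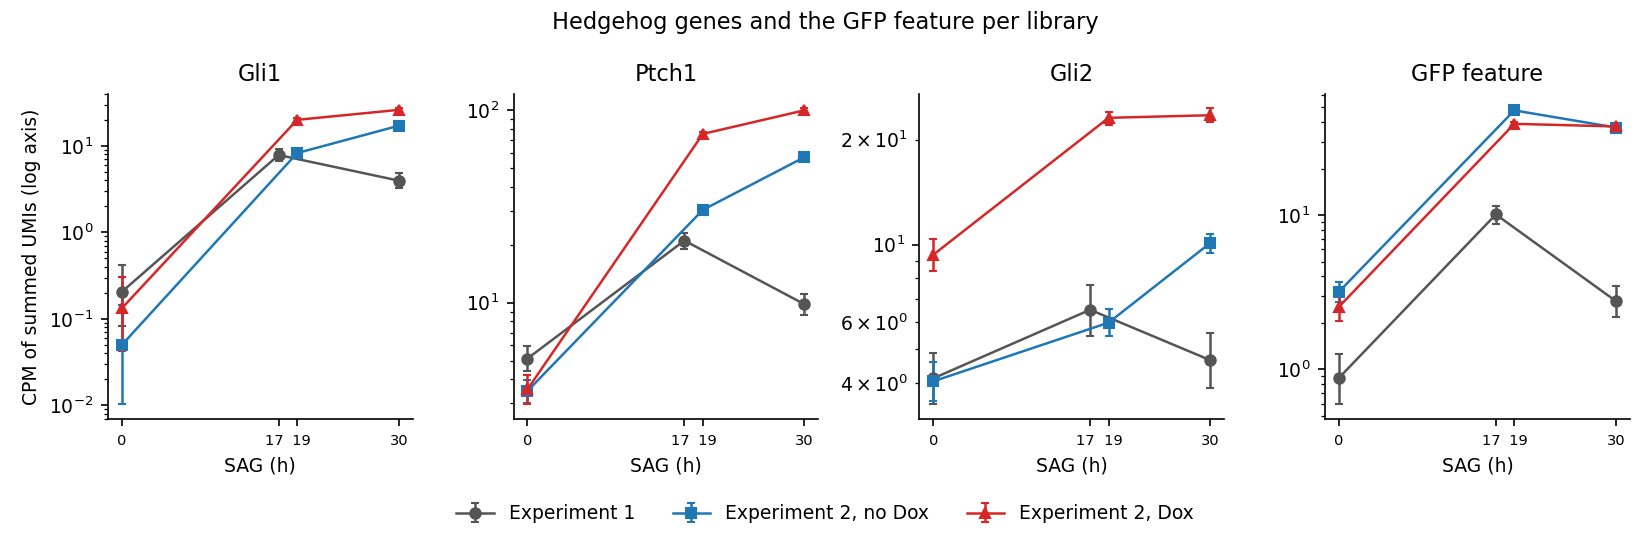
Levels of Gli1, Ptch1, Gli2 and the GFP_g1 feature in CPM (log axis) against hours of SAG, for Experiment 1 and for Experiment 2 without and with Dox; points are single libraries and bars are 95% Poisson counting intervals. At 30 h Gli1 stood at 3.97 CPM in Experiment 1, 17.1 in Experiment 2 and 26.1 in Experiment 2 with Dox, from 0.0498 to 0.205 at 0 h.

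Outside the pathway, Col4a1 and Col4a2, the neighbouring genes of the main type IV collagen chains on chromosome 8 (11198423 to 11312826 and 11312805 to 11449287), rose by 1.89 (SE 0.40, adjusted p = 0.0173) and 1.57 (SE 0.36, adjusted p = 0.0349). Tgm2, a transglutaminase that crosslinks matrix proteins, rose by 1.71 (SE 0.36, adjusted p = 0.0173), Scara5, a ferritin receptor, by 1.79 (SE 0.36, adjusted p = 0.0129) and Lactb, a mitochondrial protease, by 1.44 (SE 0.29, adjusted p = 0.0105). Within Experiment 1 these rises were small: 0.52 for Col4a1, 0.32 for Col4a2, 0.27 for Tgm2, 0.40 for Scara5 and 0.62 for Lactb. Within Experiment 2 they were 3.01, 2.63, 2.84, 2.90 and 2.26 in the same order. The acute-phase gene Saa3 (chromosome 7, 46711998 to 46715700) fell by 4.84 (SE 0.83, adjusted p = 0.00207), with -0.52 within Experiment 1 and -6.91 within Experiment 2. Ccl2, a monocyte chemoattractant, fell by 1.95 (SE 0.27, adjusted p = 0.000106), with -1.57 and -2.32, and Thbs1, thrombospondin 1, fell by 1.32 (SE 0.27, adjusted p = 0.015), with -1.39 and -1.19. Bc1, a short noncoding RNA, fell by 3.16 (SE 0.39, adjusted p = 2.09e-05), from 359.97 to 41.04 CPM in Experiment 2, while Experiment 1 held 0.117 CPM or less. Rpa3, a subunit of the single-strand binding complex of DNA replication, fell by 1.39 (SE 0.26, adjusted p = 0.00566), with -0.96 and -1.69. Snhg9, a small nucleolar RNA host gene, fell by 1.90 (adjusted p = 0.00658), B930036N10Rik, of unknown function, by 1.91 (adjusted p = 0.0336) and Ctla2b, a cysteine protease inhibitor gene, by 1.46 (adjusted p = 0.0363), with -0.41, -0.03 and -0.35 within Experiment 1 and -2.53, -3.18 and -1.60 within Experiment 2.

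In total 64 of 14354 genes were called at 30 h, 20 higher and 44 lower, and 52 of them had the same direction in both experiments. DESeq2 called 12, of which 11 were shared. In edgeR without the experiment as a block 0 genes were called (85 at unadjusted p under 0.05). Without the Experiment 2 library at 30 h, Gli1 was the 1 gene called, with Ptch1 at 1.22 (adjusted p = 1), GFP_g1 at 1.80 (adjusted p = 0.282) and Ccl2 at -1.52 (adjusted p = 0.282). Without the Experiment 2 library at 0 h 37 genes were called, and Col4a1 (1.18), Scara5 (1.04), Col4a2 (0.90), Lactb (0.90), Tgm2 (0.62), Bc1 (-1.64), Rpa3 (-0.88), Saa3 (-0.88), Snhg9 (-0.41), B930036N10Rik (-0.22) and Ctla2b (-0.03) were not (adjusted p of 0.519 or more). Without the Experiment 1 library at 0 h 1276 genes were called and without that at 30 h 289, and Gli2 then passed at 1.02 (adjusted p = 0.0143) and 1.29 (adjusted p = 0.0293). Without that at 17 h, or the Experiment 2 library at 19 h, the calls of Thbs1 (adjusted p = 0.0812 and 0.0804) and Ctla2b (0.0966 and 0.0959) ended with their values in place.

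Of the lists of genes drawn up from general knowledge, that of Hedgehog targets had 4 of 27 measured genes called higher at 30 h and 0 lower: Gli1, Ptch1, Hsd11b1, a glucocorticoid-activating enzyme (2.58, SE 0.49, adjusted p = 0.00724), and the growth factor gene Igf1 (1.70, SE 0.39, adjusted p = 0.0356). Adjusted over the list alone, 6 were higher and 1 lower. The median of the list was -0.05 within Experiment 1 and 0.53 within Experiment 2. The list test of camera with its preset correlation gave an adjusted p of 0.035 for the targets, and adjusted p = 0.843 with an estimated correlation. The NF-kB and chemokine list had medians of -0.52 and -0.73 within the experiments, with 4 of 18 called lower: Ccl2, Saa3, Cxcl1 (-2.30, SE 0.41, adjusted p = 0.00304) and Cxcl5 (-1.55, SE 0.31, adjusted p = 0.0137), both neutrophil attractants. Adjusted over the list alone, 9 were lower, and the list test gave an adjusted p of 9.96e-06, and adjusted p = 0.778 with an estimated correlation. Immediate early genes had 0 of 24 called by edgeR and 0 by DESeq2, with 1 higher and 10 lower at unadjusted p under 0.05. Adjusted over the list alone, 1 was higher and 9 lower, and the list test gave an adjusted p of 0.000468, and adjusted p = 0.843 with an estimated correlation. The median of this list was -1.04 within Experiment 1 and 0.13 within Experiment 2. Fosb and Fos, subunits of the AP-1 factor, stood at -1.58 (SE 0.38, adjusted p = 0.0523) and -1.80 (SE 0.44, adjusted p = 0.0571), with -2.58 and -3.06 within Experiment 1 and -0.29 and 0.02 within Experiment 2.

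The Hedgehog pathway components had 0 of 35 genes called at 30 h by edgeR and DESeq2, with 5 higher and 1 lower at unadjusted p under 0.05, and Grk2, a kinase that acts on Smoothened, stood at 0.70 (SE 0.23, adjusted p = 0.204). The mitochondrially encoded genes had 0 of 13 called by edgeR and DESeq2, with 4 lower at unadjusted p under 0.05. Adjusted over the list alone, 2 were lower, and mt-Nd4l, a subunit of respiratory complex I, stood at -1.95 (SE 0.48, adjusted p = 0.0571), with -0.07 within Experiment 1 and -3.38 within Experiment 2. Cholesterol synthesis genes had 0 of 23 called by both tools (1 lower at unadjusted p under 0.05) and ribosomal protein genes 0 of 40 (0 at unadjusted p under 0.05), with medians of -0.19 and -0.23. The list tests of these groups gave adjusted p of 0.0449 for the components, upward, and 0.0044, 0.035 and 0.0279 for the mitochondrial, cholesterol and ribosomal lists, downward. With an estimated correlation none of them passed (adjusted p = 0.843 for the first 3 and 0.85 for the ribosomal list). The experiments differed in sign in each of these lists: the medians within Experiment 1 and then Experiment 2 were -0.05 and 0.54 for the components, 0.17 and -1.27 for the mitochondrial, -0.55 and 0.14 for the cholesterol and 0.24 and -0.64 for the ribosomal list. Kept cells under 1% mitochondrial UMIs made up 0.6% of Experiment 2 at 0 h and 19.7% at 30 h without Dox, and 0.4% and 0.9% in Experiment 1. In Experiment 2 at 30 h without Dox these cells held more ribosomal protein UMIs (38.27%) than those of 1% to 10% mitochondrial UMIs (34.63%). The remaining 17 lists did not pass. Among them, 2 of 37 extracellular matrix genes were called higher (Col4a1, Col4a2) and 1 lower (Thbs1), against 3 and 3 adjusted over the list alone, and Dkk2, a Wnt antagonist, was the 1 of 13 Wnt genes called, at -1.84 (SE 0.32, adjusted p = 0.00222). The direction of the test and the sign of the median differed for the G2 to M, extracellular matrix, Wnt and quiescence lists, none of which passed.

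At 17 to 19 h of SAG the pathway was on in both experiments by amounts nearer to each other. Gli1 rose by 6.28 (SE 0.53, adjusted p = 7.36e-09, n = 2 libraries per time), with 5.05 within Experiment 1 and 6.65 within Experiment 2, to 7.84 and 8.26 CPM. GFP_g1 counts rose by 3.79 (SE 0.33, adjusted p = 1.04e-08), with 3.47 and 3.89. Ptch1 rose by 2.46 (SE 0.38, adjusted p = 0.00119), with 2.03 and 3.11. Gipc2, a PDZ-domain adaptor gene, rose by 3.36 (SE 0.42, adjusted p = 3.1e-05), with 2.78 and 4.98, and Lactb by 1.51 (SE 0.28, adjusted p = 0.0122), with 1.25 and 1.89. Fos fell by 2.19 (SE 0.45, adjusted p = 0.0345), with -3.75 within Experiment 1 and -0.29 within Experiment 2. Saa3 fell by 4.98 (adjusted p = 0.00135), with -1.11 and -6.23, Bc1 by 2.72 (adjusted p = 0.000346), with -0.26 and -2.79, and Snhg9 by 1.80 (adjusted p = 0.0298). Gli2 was not called, at 0.58 (SE 0.28, adjusted p = 1), nor were Gli3 at -0.18, Smo at -0.07 and Sufu at 0.24 (adjusted p = 1 for each).

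Of 14354 genes, 16 were called at 17 to 19 h, 8 in each direction and all with the same direction in both experiments. DESeq2 called 7, of which 6 were shared. Of 27 Hedgehog targets, 3 were called higher (Gli1, Ptch1 and Hsd11b1 at 2.42, SE 0.49, adjusted p = 0.0298), and 4 adjusted over the list alone. Of 18 NF-kB and chemokine genes, 3 were called lower: Saa3, Cxcl5 (-1.76, SE 0.32, adjusted p = 0.0103) and Ccl2 (-1.29, SE 0.26, adjusted p = 0.0313). Adjusted over the list alone, 7 were lower. Fos was the 1 immediate early gene of 24 called lower, and adjusted over the list alone 10 were lower and 1 higher. Interferon response genes had 0 of 24 called by edgeR and DESeq2 (3 lower at unadjusted p under 0.05). Adjusted over the list alone, 1 was lower, and Cxcl10, an interferon-induced chemokine, stood at -1.96 (SE 0.57, adjusted p = 0.48). These 4 lists passed with the preset correlation (adjusted p of 0.0414, 1.01e-08, 3.96e-06 and 1.5e-05). None passed with an estimated one (adjusted p = 0.974, 0.418, 0.809 and 0.418 with an estimated correlation). Their medians within Experiment 1 and then Experiment 2 were 0.06 and 0.27 for the Hedgehog targets, -0.66 and -0.45 for NF-kB, -0.87 and 0.03 for immediate early and -0.25 and -0.21 for interferon genes. Of the 20 other lists, the Wnt list had Dkk2 called, at -1.52 (SE 0.32, adjusted p = 0.0371). Gli1, GFP_g1, Gipc2 and Ptch1 stayed called whichever of the 4 libraries compared was left out. Without the Experiment 2 library at 0 h the calls of Lactb (1.03), Saa3 (-0.67), Bc1 (-1.22) and Snhg9 (-0.29) ended, without that at 19 h those of Bc1 (-0.22) and Snhg9 (-0.91), without the Experiment 1 library at 17 h those of Lactb (1.39) and Fos (-1.25), and without that at 0 h that of Fos (-0.42), with adjusted p of 0.214 or more. In all, 243 genes were called without the Experiment 1 library at 0 h, 8 without that at 17 h and 54 without the Experiment 2 library at 0 h.

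Between 17 to 19 h and 30 h Gli1, Ptch1 and Gli2 fell in Experiment 1 and rose in Experiment 2 without Dox, and 1 gene of 14354 was called. It was the replication-dependent histone gene Hist1h2ab, which fell by 2.47 (SE 0.42, adjusted p = 0.0217) from 0.231 to 0 CPM in Experiment 1 and from 7.69 to 1.57 in Experiment 2, below the level set for naming genes. DESeq2 called 0, and 418 genes had an unadjusted p under 0.05 in edgeR (113 in DESeq2). Without the Experiment 1 library at 30 h 11 genes were called, and without that at 17 h, or the Experiment 2 library at 19 h or 30 h, edgeR called 0 (98, 190 and 122 at unadjusted p under 0.05). Gli1 stood at 0.18 (SE 0.35, adjusted p = 0.999), Ptch1 at 0.14 (SE 0.36) and Gli2 at 0.21 (SE 0.27). GFP_g1 counts stood at -0.96 (SE 0.29, adjusted p = 0.999). Other genes with the smallest p were the histone genes Hist1h3b at -2.14 (SE 0.47, adjusted p = 0.361) and Hist1h3f at -2.10 (SE 0.51, adjusted p = 0.884), the olfactory receptor gene Olfr1318 at -2.69 (SE 0.57, adjusted p = 0.354), Ap3b2 at 0.86, Usp36 at 0.74, Pld3 at 0.73 and Pex6 at 0.71 (adjusted p = 0.999 for each of the last 4). No list had a called gene by either tool. With the preset correlation the mitochondrially encoded (median -0.39, adjusted p of 0.00965) and ribosomal protein genes (-0.17, 0.0288) were lower and the interferon genes higher (0.18, 0.0329), each with adjusted p = 0.948 with an estimated correlation. The medians within Experiment 1 and then Experiment 2 were -0.09 and -0.77, 0.09 and -0.40, and 0.26 and 0.22 in the same order. Beside the mitochondrial list, kept cells under 1% mitochondrial UMIs made up 1.4% at 19 h and 19.7% at 30 h in Experiment 2 without Dox. In Experiment 1 they made up 0.5% at 17 h and 0.9% at 30 h.

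With Dox the transcriptome differed widely, and Gli2, Gli1, Ptch1, Gli3 and Smo were higher. Cck, which encodes the peptide cholecystokinin (ENSMUSG00000032532, chromosome 9, 121489824 to 121495694), rose by 6.10 (SE 0.21, adjusted p = 7.74e-27, edgeR, n = 3 libraries with and 3 without Dox, matched by SAG time), with 5.23, 5.34 and 6.94 at 0, 19 and 30 h. Aspn, a small proteoglycan of the matrix (ENSMUSG00000021388, chromosome 13, 49544443 to 49567565), rose by 4.38 (SE 0.14, adjusted p = 5.94e-28), with 4.63, 4.14 and 4.34. Gli2 (ENSMUSG00000048402, chromosome 1, 118834132 to 119053619) rose by 1.47, or 2.76-fold (SE 0.13, adjusted p = 1.74e-12), with 1.2, 1.94 and 1.22 at the 3 times. Gli1 rose by 0.94, or 1.92-fold (SE 0.14, adjusted p = 1.35e-06), from 8.26 to 20.03 CPM at 19 h and from 17.1 to 26.1 at 30 h. At 0 h the Gli1 ratio of 2.66 (95% counting interval 0.517 to 17.1) rested on 3 and 5 UMIs. Ptch1 rose by 0.80, or 1.75-fold (SE 0.14, adjusted p = 2.42e-05), with 0.03 at 0 h, 1.31 at 19 h and 0.81 at 30 h. Gli3 rose by 0.59 (SE 0.11, adjusted p = 5.68e-05) and Smo by 0.54 (SE 0.12, adjusted p = 0.000379), while Sufu at -0.03 (SE 0.12, adjusted p = 0.889) and GFP_g1 at -0.18 (SE 0.12, adjusted p = 0.24) were not called.

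Among the genes that reach 10 CPM and move the same way at all 3 times, the largest rises with Dox after Cck and Aspn were those of Nrp2, a semaphorin and VEGF co-receptor (by 2.52, SE 0.12), Cdh11, a cadherin of mesenchymal cells (by 2.5, SE 0.14), Itgbl1, a secreted integrin-like protein (by 2.49, SE 0.13), Trabd2b, Mfap4, a microfibril protein (by 2.09, SE 0.13), and Col11a1, a fibrillar collagen chain (by 2.08, SE 0.14). Trabd2b, a membrane metalloprotease that inactivates Wnt ligands, rose by 2.45 (SE 0.19, adjusted p = 3.05e-14), with 0.86 at 0 h, 3.11 at 19 h and 2.59 at 30 h. The largest falls among the same genes were those of AY036118, an annotated transcript with ribosomal RNA sequence (by 2.15, SE 0.20), Spata7, a ciliary transition zone gene (by 2.05, SE 0.19), Ccl5, a T cell chemoattractant (by 1.97, SE 0.13), and Ankrd1, a target of YAP (by 1.79, SE 0.13). Flacc1 fell by 1.77 (SE 0.14), Gm43154 by 1.67 (SE 0.13), Pate14 by 1.57 (SE 0.12) and Klra4 by 1.54 (SE 0.12). The adjusted p of these falls were 8.45e-12 (Spata7) or lower, and those of the rises 5.76e-17 or lower for Nrp2, Cdh11, Itgbl1 and Mfap4 and 1.94e-16 for Col11a1. Cck without Dox was at 0.117 to 0.308 CPM in Experiment 2 but at 21.7 to 34.4 CPM in Experiment 1.

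Of 13645 genes, 5233 were called with Dox, 2617 higher and 2616 lower, and 5104 of them went the same way at all 3 times. Of these calls 778 were at least 2-fold, 476 higher and 302 lower. DESeq2 called 3892, 3831 of them shared, with an uneven split of 1687 higher and 2205 lower. With DESeq2 size factors edgeR called 2476 higher and 2797 lower. Dox was given in 1 experiment, with 1 library per time, so another difference between the arms is not separated from it. Without SAG time in the model 194 were called, and leaving out 1 library gave 2956 (without the 0 h library with Dox) to 4301, with 2974 without the 0 h library without Dox.

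Of 34 Hedgehog pathway components, 13 were called higher with Dox, 2 lower and 19 not called (15 higher and 2 lower adjusted over the list alone), the higher among them Gli2 and the coreceptor genes Gas1 (1.61, SE 0.15, adjusted p = 3.37e-12) and Cdon (1.30, SE 0.12, adjusted p = 1.59e-11). Of 48 genes of the primary cilium, which houses the pathway, 19 were higher, 2 lower and 27 not called (19 higher and 3 lower adjusted over the list alone), the higher with the transition zone gene Rpgrip1l (0.80, SE 0.12, adjusted p = 4.4e-07), the transport genes Wdr35 (0.76) and Ift80 (0.76), and Bbs1 (1.02). Of 26 Hedgehog targets, 11 were higher and 4 lower (12 and 4 adjusted over the list alone), with Cdh11, Igf1 (1.76, SE 0.18, adjusted p = 2.07e-10), Ccnd1, cyclin D1 (1.08, SE 0.12), and Foxf2 (0.92). The target list did not pass the list test (adjusted p of 0.0594). Wnt targets and antagonists had 7 of 11 higher (7 adjusted over the list alone), such as the ligand gene Wnt5a (1.68, SE 0.12, adjusted p = 1.56e-15) and Dkk3 (1.39). Of 18 quiescence and FOXO targets, 10 were higher (11 adjusted over the list alone), such as Gas6, a growth arrest ligand (1.78), Sesn3 (0.93) and Pdgfra (0.81). Of 35 extracellular matrix genes, 20 were higher and 4 lower (21 and 5 adjusted over the list alone), with Col11a1, Thbs2 (1.67), Col6a3 (1.21) and Col4a2 (1.18). Cells with at least 3 smooth muscle or myofibroblast markers made up 2.37%, 2.87% and 3.86% without Dox and 4.91%, 6.15% and 9.29% with Dox at 0, 19 and 30 h. Of these markers Myl9 alone was called higher with Dox (0.79). Acta2 at -0.05, Tagln at -0.29, Cnn1 at 0.51, Myh11 at 0.15 and Actg2 at 0.34 were not called (edgeR, adjusted p of 0.0702 or more). The list tests with the preset correlation gave adjusted p of 0.00616 for the components, 0.000859 for cilium, 0.000357 for Wnt, 0.00497 for quiescence and 0.00152 for matrix genes. With an estimated correlation they gave adjusted p = 0.499, and adjusted p = 0.434 for the Wnt list. The medians at 0, 19 and 30 h were 0.19, 0.40 and 0.11 for the components, 0.33, 0.20 and 0.23 for cilium, 0.50, 0.86 and 0.70 for Wnt, 0.37, 0.43 and 0.20 for quiescence and 0.57, 0.52 and 0.11 for matrix genes.

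Of 47 G2 to M genes, 33 were called lower with Dox and 1 higher (35 and 1 adjusted over the list alone), with Ube2c, a ubiquitin-conjugating enzyme of mitosis, at -1.26 (SE 0.12, adjusted p = 5.64e-12), the spindle gene Nusap1 at -1.22, Cenpa at -0.80 and Cks2 at -0.80. Mki67 at -0.06 (SE 0.11, adjusted p = 0.698) and Top2a at -0.26 (SE 0.14, adjusted p = 0.139) were not called. Of 44 G1 to S genes, 14 were lower and 1 higher (the same counts adjusted over the list alone), such as Gmnn (-0.86), Hells (-0.76) and Tipin (-0.42). Of 29 ATF4 and integrated stress response genes, 17 were lower and 0 higher (20 and 0 adjusted over the list alone), with the factor gene Ddit3 (ENSMUSG00000025408) at -1.32 (SE 0.13, adjusted p = 8.7e-11), the cystine transporter gene Slc7a11 at -1.02, Nupr1 at -0.87 and Chac1 at -0.71. Of 19 ER stress genes, 9 were lower (10 adjusted over the list alone), such as Manf (-0.75) and the chaperone gene Hspa5 (-0.73). Of 23 glycolysis and hypoxia genes, 19 were lower (19 adjusted over the list alone), with Ero1l at -1.13 (SE 0.12), the glycolytic enzyme gene Pgk1 at -1.03, Ankrd37 at -0.94 and Bnip3 at -0.90. Of 40 ribosomal protein genes, 39 were lower (40 adjusted over the list alone), such as Rps2 (-0.83) and Rpl37 (-0.81). Their adjusted p in the list tests were 1.12e-09 for G2 to M, 0.00147 for G1 to S, 1.89e-06 for ATF4, 0.000357 for ER stress, 8.4e-08 for glycolysis and 6.7e-14 for ribosomal genes. With an estimated correlation they were adjusted p = 0.499, 0.578, 0.343, 0.434, 0.343 and 0.499 in the same order. The medians at 0, 19 and 30 h were -0.59, -0.64 and -0.37 for G2 to M, -0.44, -0.25 and 0.05 for G1 to S, -0.39, -0.38 and -0.46 for ATF4, -0.23, -0.40 and -0.36 for ER stress, -0.58, -0.61 and -0.47 for glycolysis and -0.47, -0.91 and -0.46 for ribosomal genes.

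Of 13 mitochondrially encoded genes 10 were called lower with Dox (10 adjusted over the list alone), with mt-Nd6 at -1.38 (SE 0.18, adjusted p = 9.22e-08), and of 37 nuclear genes of the respiratory chain 18 (19 adjusted over the list alone), with Uqcrq at -0.60. Of 24 interferon response genes, 14 were lower and 1 higher (15 and 2 adjusted over the list alone), such as Usp18 (-1.56), Ifit1 (-1.37, SE 0.14, adjusted p = 7.72e-11) and the ubiquitin-like Isg15 (-1.18). Of 23 cholesterol synthesis genes, 8 were lower and 1 higher (9 and 1 adjusted over the list alone), such as Idi1 (-0.65) and Fdps (-0.61). Their list tests gave adjusted p of 0.000302, 2.31e-05, 0.00013 and 0.00212 in this order, each with adjusted p = 0.499 with an estimated correlation. The medians at 0, 19 and 30 h were -0.46, -0.97 and -0.21 for the mitochondrially encoded, -0.23, -0.52 and -0.17 for the nuclear respiratory chain, -0.59, -0.42 and -0.54 for the interferon and -0.22, -0.35 and -0.21 for the cholesterol genes. The share of mitochondrial UMIs in kept cells, which uses no TMM factors, did not fall at each time. Its median with and then without Dox was 7.74% and 7.6% at 0 h, 6.25% and 6.77% at 19 h and 6.19% and 5.47% at 30 h. At 30 h the mitochondrial limit had removed 46.3% of the barcodes with at least 5000 UMIs with Dox and 25.9% without. The fall of the mitochondrially encoded list thus holds for the kept cells and this normalization. The mitochondrially encoded and ribosomal lists had their lowest medians at 19 h. Kept cells under 1% mitochondrial UMIs then made up 18.2% with Dox and 1.4% without, and at 30 h 17.9% and 19.7%. At 19 h with Dox these cells held more ribosomal protein UMIs (33.63%) than those of 1% to 10% mitochondrial UMIs (29.01%). At 30 h they held 32.54% against 29.19% with Dox and 38.27% against 34.63% without. These values argue against such cells as the source of the ribosomal fall.

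The remaining 8 lists had calls on both sides and did not pass the list test with Dox (adjusted p of 0.184 to 0.746), with the counts given higher before lower. NF-kB and chemokine genes had 10 and 2 of 18 (10 and 2 adjusted over the list alone), with Saa3 at 2.14 and Cxcl5 at 1.25 against Lcn2 at -2.29 and Ccl5. TGF-beta and BMP targets had 8 and 4 of 17 (8 and 6 adjusted over the list alone), with Ltbp2 at 1.99, Pmepa1 at 1.23 and Tgfbi at 1.05 against Id3 at -1.01. Immediate early genes had 5 and 9 of 23 (6 and 9 adjusted over the list alone), with Ccn2 at 1.13, Nr4a1 at 1.11 and Egr1 at 0.93 against Myc at -0.87. Contractile and SRF targets had 3 and 4 of 18 (3 and 4 adjusted over the list alone), with Lmod1 at 1.52 and Myl9 at 0.79 against Ankrd1 and Tpm2 at -0.65. Adipogenesis genes had 5 and 2 of 14 (5 and 2 adjusted over the list alone), with Fabp4 at 1.90 and Cebpd at 0.97 against Plin2 at -0.55. Targets of p53 had 4 and 1 of 19 (3 and 1 adjusted over the list alone), with the cyclin-dependent kinase inhibitor gene Cdkn1a at 0.76 against Plk2 at -0.62. Heat shock genes had 4 and 5 of 12 (4 and 5 adjusted over the list alone), with Hspa1b at 0.66 against Hspd1 at -0.58. NRF2 targets had 4 and 6 of 19 (4 and 7 adjusted over the list alone), with Prdx1 at -0.62 and Tkt at -0.61 among the lower. With fry, which asks whether the genes of a list move on balance to 1 side, 6 lists passed with Dox, 4 of them among the 15 that passed with camera.

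**Figure D2:**
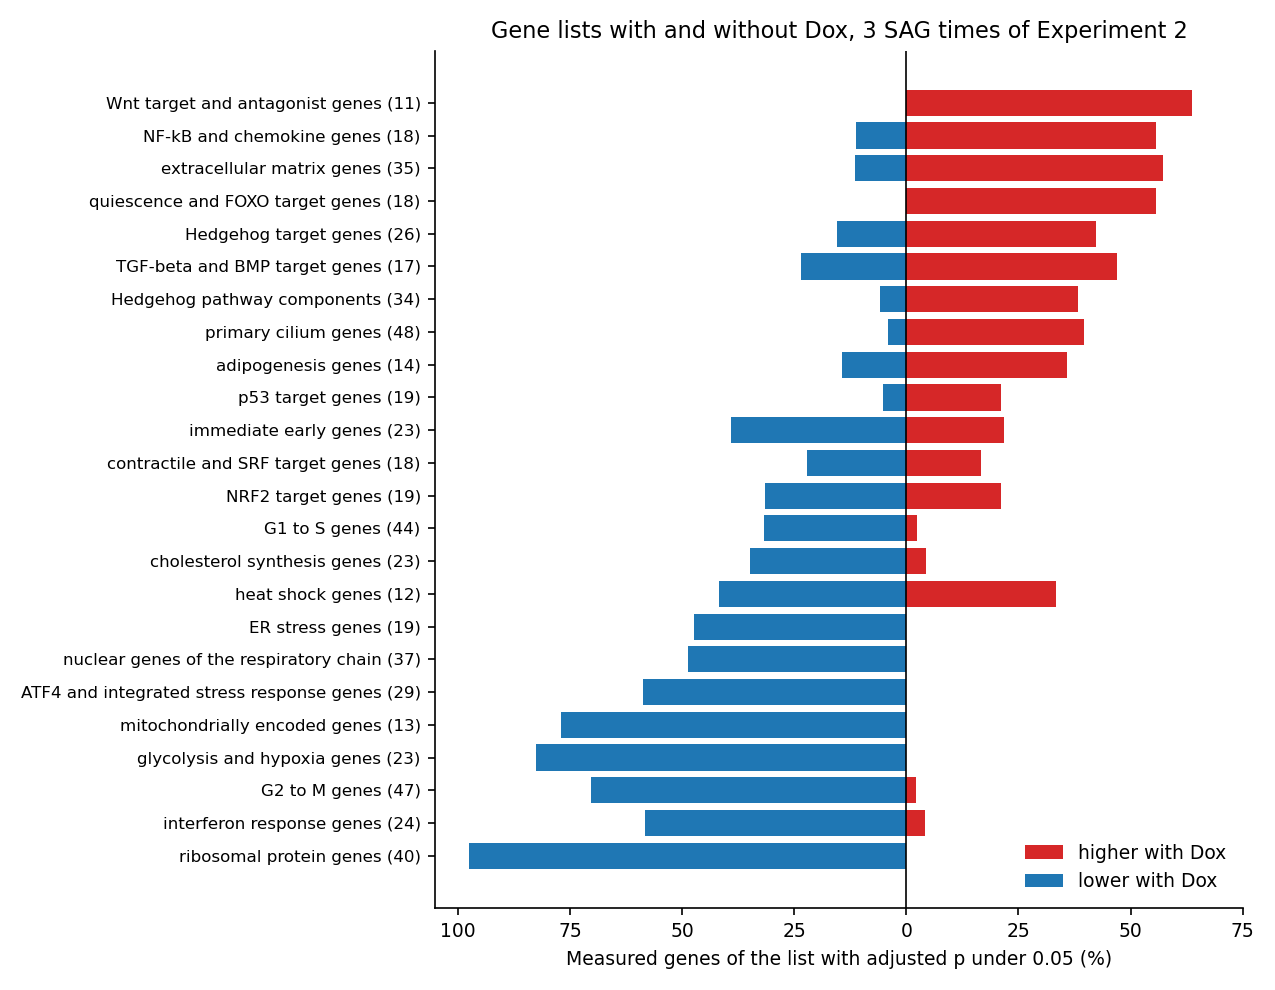
Percent of the measured genes of each of the 24 gene lists called higher (right) or lower (left) with Dox in Experiment 2 (edgeR, 3 libraries with and 3 without Dox, adjusted p under 0.05), in the order of the median change, with the number of measured genes in brackets. Of the ribosomal protein genes 39 of 40 were lower, and of the Wnt genes 7 of 11 were higher.

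The SAG response itself differed with Dox at 1 called gene of 14354. Trabd2b (ENSMUSG00000070867, chromosome 4, 114406724 to 114615098) responded more with Dox by 3.02 (SE 0.52, adjusted p = 0.0331), as the mean of 17 to 19 h and 30 h against 0 h. In Experiment 2 it went from 1.33 to 2.93 and 6.13 CPM without Dox and from 2.43 to 25.5 and 37.0 CPM with Dox, at 0, 19 and 30 h, while in Experiment 1 it was at 3.19, 2.03 and 2.96 CPM. The difference was 2.04 for Ptch1 (SE 0.58, adjusted p = 1), 1.0 for Gli1 (SE 1.08, adjusted p = 1) and 0.59 for Gli2 (SE 0.40, adjusted p = 1), and these were not called. The response without Dox here is that of both experiments. In Experiment 2 alone, which has 1 library per arm and time, a fit that takes the difference as the same at 19 h and 30 h leaves 1 residual degree of freedom and rests on single libraries at 0 h. There the difference was 1.99 for Trabd2b (adjusted p = 0.00013), 1.05 for Ptch1 (adjusted p = 0.758), -0.43 for Gli1 (adjusted p = 1) and 0.39 for Gli2 (adjusted p = 1), with 30 genes called. The call of Trabd2b ended without the 30 h library of Experiment 1 (2.62, adjusted p = 0.678) or of Experiment 2 without Dox (3.28, adjusted p = 0.0578) (0 and 5 genes called in all). It also ended, with values of 2.91 to 3.09, with at least 2000 UMIs (adjusted p = 0.0926), without cells above 2.5 times the median UMI count (0.398), without scrublet doublets (0.0758), with DESeq2 size factors (0.217) and with libraries thinned to the same total (0.117). In all, 256 were called without the Experiment 2 library at 0 h without Dox, 7 without that of Experiment 1 at 0 h and 4 without that at 17 h. Ptch1 passed without the Experiment 2 library at 0 h without Dox (2.98, adjusted p = 1.55e-08) or at 30 h without Dox (2.64, adjusted p = 0.0451).

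Across cells, the share of cells in which Gli1 was caught was higher with SAG in each arm. At 10000 UMIs per cell, the share of cells with a Gli1 UMI in Experiment 1 was 0.109% of 917 cells at 0 h (exact binomial 95% interval 0.00276 to 0.606), 7.18% of 543 at 17 h (5.16 to 9.69) and 4.29% of 559 at 30 h (2.77 to 6.32). In Experiment 2 without Dox it was 0 of 2658 cells at 0 h, which allows up to 0.139%, 7.32% of 2610 at 19 h (6.35 to 8.39) and 16.8% of 2047 at 30 h (15.2 to 18.5). With Dox it was 0.0755% of 1324 (0.00191 to 0.42), 20.2% of 1935 (18.4 to 22.1) and 26.8% of 1529 (24.6 to 29.1). The untreated libraries give the share without SAG and cannot measure free Gli1 RNA in the treated ones, which stays open: barcodes under 5000 UMIs of the treated libraries held Gli1 at 7.98 to 37.8 CPM. The change from 0 h to 30 h was 4.18, 16.8 and 26.7 percentage points in the 3 arms, with a mean of 15.9. No p was computed, since 3 arms cannot reach 0.05 in an exact sign test. The intervals treat cells as independent draws, as do all intervals here, and cover counting error only.

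**Figure D3:**
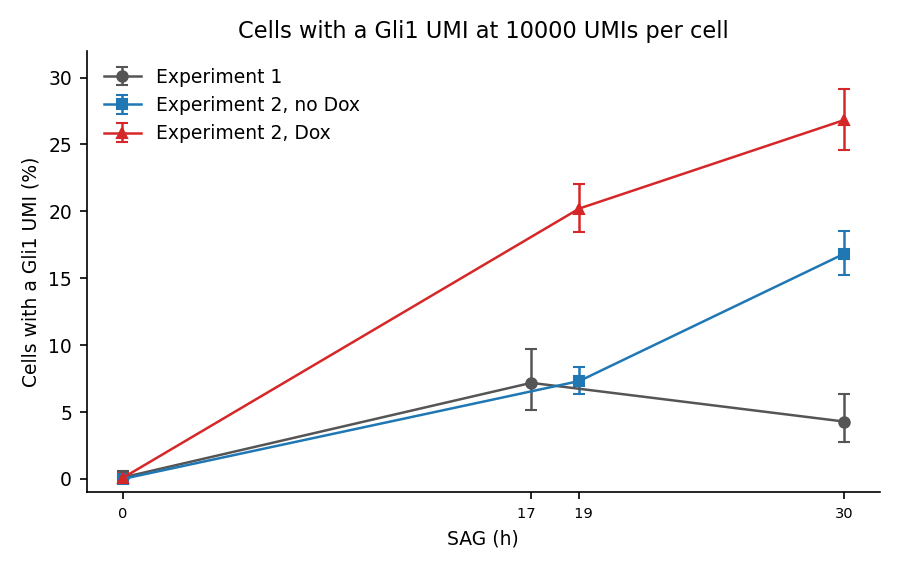
Percent of kept cells with a Gli1 UMI after thinning each cell to 10000 UMIs, against hours of SAG, for Experiment 1 and for Experiment 2 without and with Dox; bars are exact binomial 95% intervals. The share at 30 h was 4.29% in Experiment 1, 16.8% in Experiment 2 and 26.8% in Experiment 2 with Dox.

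At 10000 UMIs per cell, Gli1 counts varied between cells somewhat more than random capture gives, in 3 of the 6 SAG-treated libraries. The variance beyond Poisson, divided by the squared mean, was 0.683 (95% interval from resampled cells 0.308 to 1.10) in Experiment 2 at 30 h, 0.298 (0.0258 to 0.597) at 19 h with Dox and 0.253 (0.00447 to 0.524) at 30 h with Dox. It was 0.868 (-0.0439 to 1.98) in Experiment 2 at 19 h and 0.872 (-0.974 to 3.0) in Experiment 1 at 17 h. In Experiment 1 at 30 h it was -0.960, on 24 cells with 1 UMI each, and the mean of the 6 libraries was 0.336. Among the 200 genes nearest in mean count, Gli1 stood at the 16.5 to 89.5 percentile over the 6 libraries. Ptch1 had excesses of 1.26, 0.963, 1.15, 1.04, 0.529 and 0.652 in Experiment 1 at 17 and 30 h and in Experiment 2 at 19 and 30 h without and then with Dox.

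The link of Gli2 with Gli1 across cells, which bears on the transcription factor fluctuations in the series title, did not pass at the depth set beforehand and passed in the full counts. In cells thinned to 10000 UMIs the correlation (Pearson's r of log counts) of Gli2 with Gli1 was 0.173 and -0.0097 in Experiment 1 at 17 and 30 h, 0.0104 and 0.0808 in Experiment 2 at 19 and 30 h, and 0.0556 and 0.00511 with Dox. The mean was 0.0525, above 0 in 5 of 6 libraries (exact sign-flip permutation test, two-sided, p = 0.0938, the smallest possible being 0.0312). Cells with a Gli2 UMI held 1.60 times as many Gli1 UMIs as the others, as the mean over libraries. That mean leans on Experiment 1 at 17 h, with a ratio of 3.73. The remaining libraries had ratios of 0.825 (Experiment 1 at 30 h) to 1.58 (Experiment 2 at 30 h without Dox). In the full counts the mean r was 0.127 and above 0 in 6 of 6 libraries (exact sign-flip p = 0.0312), 0.126 given the UMI count of the cell (exact sign-flip p = 0.0312), and at 20000 UMIs per cell it was 0.0871 (exact sign-flip p = 0.0312). Without Experiment 1 at 17 h the mean at 10000 UMIs was 0.0285, and with another random thinning of all 6 it was 0.0279 (exact sign-flip p = 0.219). Among the 200 genes nearest in mean count, Gli2 had a median percentile of 81.75 at 10000 UMIs and 99.5 in the full counts. Few UMIs keep r low: in simulated counts with rates set to be correlated the mean r was 0.084 and 0.161 (0.002 and -0.001 with the rates shuffled), so the size of r does not measure the link of the rates. The simulated genes had higher mean counts than Gli1 and Gli2 had at 10000 UMIs in any of the 6 libraries. Their r thus cannot be set against the 0.0525. Ptch1 had a median r of 0.118 with Gli1 over the same 6 libraries. In the untreated libraries the r of Gli2 with Gli1 was -0.0081 and -0.00786 in those 2 that held a Gli1 UMI.

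**Figure D4:**
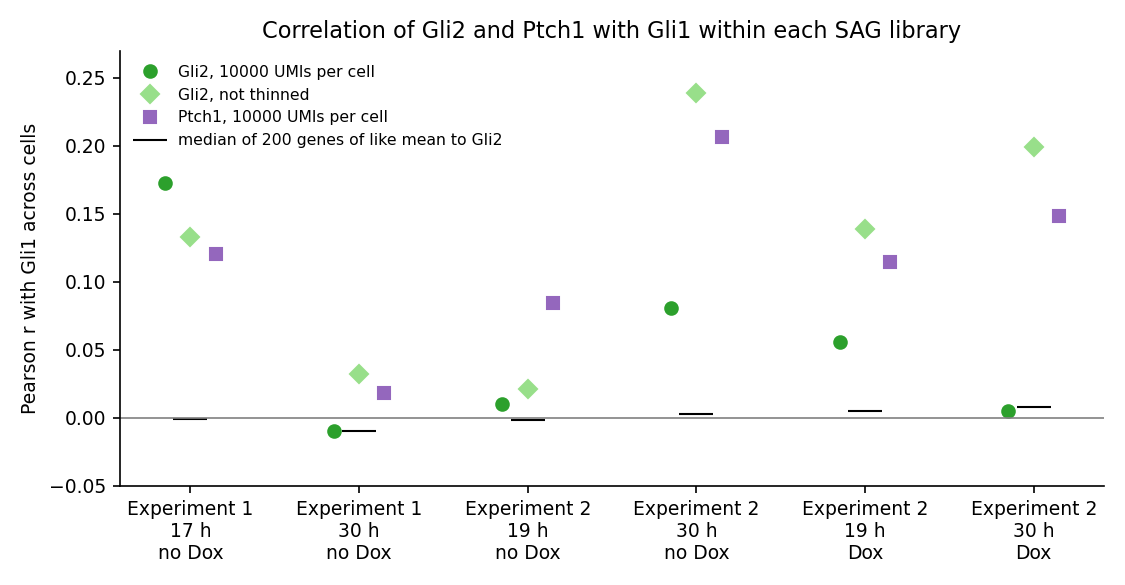
Pearson's r of Gli2 and of Ptch1 with Gli1 across the cells of each of the 6 SAG-treated libraries, thinned to 10000 UMIs per cell (Gli2 also unthinned), with dashes at the median of the 200 genes nearest to Gli2 in mean count. The mean r of Gli2 over libraries was 0.0525 thinned and 0.127 unthinned.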

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

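The test with cells of 1% to 10% mitochondrial UMIs was chosen only after the data were seen. Trabd2b stood out because its SAG response differed with Dox in a test of that difference, by 3.02 on the log2 scale (edgeR, SE 0.52, adjusted p = 0.0331). Of the gene lists, the difference in SAG response had a median of 0.54 for the Hedgehog targets and of -0.60 for the mitochondrially encoded, -0.30 for the nuclear respiratory chain and -0.56 for the ribosomal protein genes. These 4 lists passed with camera's preset correlation (adjusted p of 0.00342, 0.000684, 0.0157 and 2.17e-09), and each had adjusted p = 0.979 with an estimated correlation. The response without Dox was taken from both experiments. Within Experiment 2 the medians were 0.15, -0.15, -0.13 and -0.18 in the same order, and Trabd2b was at 1.99. Beside the mitochondrial list, kept cells under 1% mitochondrial UMIs made up 18.2% with Dox and 1.4% without at 19 h of Experiment 2. At 30 h they made up 17.9% and 19.7%, and in Experiment 1 0.4% to 0.9%. Igf1 was the Hedgehog target with the smallest p, at 2.43 (SE 0.64, adjusted p = 1).

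From 17 or 19 h to 30 h Gli1, Ptch1 and Gli2 moved in opposite directions in Experiment 1 and in Experiment 2 without Dox, a difference that was not tested. Gli1 changed by -0.98 (95% counting interval -1.35 to -0.62) in Experiment 1, by 1.05 (0.92 to 1.18) in Experiment 2 without Dox and by 0.38 (0.29 to 0.47) with Dox. Ptch1 changed by -1.10, 0.91 and 0.41 in the same order, and Gli2 by -0.48, 0.75 and 0.03, the last with an interval of -0.06 to 0.12. GFP_g1 counts changed by -1.86, -0.37 (-0.43 to -0.30) and -0.06 (-0.12 to 0.01). These intervals cover counting error in single libraries and not the spread between cultures.

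Barcodes under 5000 UMIs, which were not among the kept cells, also carried Gli1. Its level there was 7.98 CPM of their own UMIs (95% counting interval 7.22 to 8.8) in Experiment 2 at 19 h and 13.6 CPM (8.06 to 21.5) at 30 h without Dox. With Dox it was 18.0 CPM (12.6 to 24.9) at 19 h and 37.8 CPM (24.4 to 55.8) at 30 h. The untreated libraries had 0 Gli1 UMIs in such barcodes, which allows up to 0.487 CPM in Experiment 2, 8.92 CPM with Dox and 22.0 CPM in Experiment 1. Kept cells of the same 4 treated libraries had 6.6, 16.49, 23.29 and 30.16 CPM on this scale.

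The change from 0 h to 30 h of SAG was compared across 6932 genes, which are not independent of each other. It was alike in both arms of Experiment 2 (r = 0.926) and unlike between Experiment 1 and either arm (r = 0.038 and 0.064). The 11 Hedgehog targets among them had r of 0.967 between the arms and of 0.88 and 0.854 between Experiment 1 and either arm. An r over 11 genes can rest on a few large changes and does not mean that the targets moved alike. Of the 27 measured targets 10 were higher and 14 lower in Experiment 1 (median -0.05). In Experiment 2 without Dox 22 were higher and 5 lower (median 0.53). Over all genes compared, with at most 20% mitochondrial UMIs, the r between Experiment 1 and either arm was 0.134 and 0.157. Without mitochondrial and ribosomal protein genes it was 0.074 and 0.097. Barcodes with under 1% mitochondrial UMIs are argued against, since the r between the arms was 0.925 with cells of 1% to 10%. The total depth of the libraries is argued against too, since it was 0.907 with the libraries thinned to the same total. This thinning of summed counts cannot speak to depth per cell. The median UMIs per kept cell rose from 0 h to 30 h in Experiment 2 without Dox (28335 to 48188) and with Dox (29144 to 45291), and in Experiment 1 (29327 to 40905). A shared state of the untreated libraries of Experiment 2 at harvest may account for the pattern and stays open: the change from 19 h to 30 h, which uses none of them, had r = 0.502, between the bounds set for and against. A SAG response of different strength in the experiments also stays open, since of 302 genes changed over 2-fold the same way in both arms 180, or 59.6% (exact 95% interval 53.8 to 65.2), moved the same way in Experiment 1, where the median change was 0.06 for the 172 higher and -0.06 for the 130 lower genes. A real difference between the experiments in what SAG changes was not tested and stays open too. So does a change with time in culture rather than with SAG, which this design cannot separate.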

How the results depend on the processing

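The tests with at most 20% or with 1% to 10% mitochondrial UMIs, at 20000 UMIs per cell, given the UMI count, in the cells lowest in cell cycle counts and without the 17 h or 19 h library at 30 h were chosen only after the data were seen. Counts of called genes are given for 30 h, 17 to 19 h, 30 h against 17 to 19 h, Dox and the Dox difference in SAG response, whose counts were 64, 16, 1, 5233 and 1. Where a setting is not given for a comparison, its count was within 1.5 times of that. Except where a cause is named, the cause was not tested.

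With every deposited barcode 175, 34, 4 and 5 genes were called at 30 h, at 17 to 19 h, between them and for the Dox difference. With at least 2000 UMIs 42 were called at 30 h and 0 for the Dox difference (283 at unadjusted p under 0.05). With at least 10000 UMIs 0 were called between the times (303 at unadjusted p under 0.05) and 2 for the difference. Leaving out cells above 2.5 times the median UMI count gave 21, 7 and 0 at 30 h, at 17 to 19 h and for the difference (228 at unadjusted p under 0.05 for the last). Leaving out scrublet doublets gave 42 at 30 h and 0 for the difference (279 at unadjusted p under 0.05). With at most 20% mitochondrial UMIs 237, 43, 9 and 9 were called at 30 h, at 17 to 19 h, between them and for the difference.

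DESeq2 size factors in edgeR gave 30, 9, 0 and 0 at 30 h, at 17 to 19 h, between them and for the difference (381 and 262 at unadjusted p under 0.05 for the last pair). The DESeq2 Wald test gave 12, 7 and 0 for the SAG comparisons (113 at unadjusted p under 0.05 for the last). With no gene filter, which tests more genes, 210, 43, 16 and 15 were called at 30 h, at 17 to 19 h, between them and for the difference. With a mean of at least 10 CPM, which tests 7007 genes for SAG, 36 were called at 30 h, 0 between the times (154 at unadjusted p under 0.05), 2744 with Dox and 3 for the difference. Thinning the libraries to the same total gave 29 at 30 h, 0 between the times (309 at unadjusted p under 0.05) and 0 for the difference (300).

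An additive model of time, Dox and experiment gave 785, 3 and 0 for the SAG comparisons (675 at unadjusted p under 0.05 for the last). Without the experiment as a replicate block edgeR called 0, 0 and 0 (85, 35 and 9 at unadjusted p under 0.05). With Dox, 778 genes passed with a change of at least 2-fold, 981 in a fit of all 9 libraries, 972 of them called before, and 194 without SAG time as a term. Experiment 2 alone gave 30 genes for the difference. Leaving out 1 library gave 1 to 1276 genes at 30 h, 8 to 243 at 17 to 19 h, 0 to 11 between the times, 2956 to 4301 with Dox and 0 to 256 for the difference. The 1 came without the Experiment 2 library at 30 h, and the 1276 without the Experiment 1 library at 0 h.

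Of 24 lists, 7, 4, 3, 15 and 4 passed in the 5 comparisons with camera's preset correlation, and with an estimated correlation 0, 0, 0, 0 and 0 did. The estimated form rests on 2 residual degrees of freedom. The NF-kB list at 30 h had an estimated correlation of 0.001, with unadjusted camera p of 4.15e-07 (preset) and 0.0324 (estimated). ATF4 genes with Dox had -0.023, with 3.15e-07 and 0.0286. Others were above the preset 0.01, such as ribosomal genes with Dox (0.787). These failures thus cannot tell whether correlation between genes explains the results. With fry 0, 0, 0, 6 and 0 passed, and with fry in either direction 0, 0, 0, 21 and 0. Calls of named genes were counted once per gene and setting. The call stayed in 268 and ended in 80 such pairs at 30 h, 138 and 40 at 17 to 19 h, and 474 and 21 with Dox. It stayed in 10 and ended in 9 between the times, and in 14 and 7 for the difference. The setting of at least 2-fold counted each call as kept whatever its size, 22 of them with Dox. None changed direction.

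Depth set the share of cells with a Gli1 UMI. The change to 30 h averaged over arms was 42.7 points unthinned against 15.9. In Experiment 1 it was 2.12 points at 5000 UMIs per cell, 7.09 at 20000, 13.1 unthinned and 1.59 with at most 5% mitochondrial UMIs, against 4.18. In Experiment 2 without Dox it was 9.37, 27.8 and 47.1 at 5000 UMIs, 20000 UMIs and unthinned, against 16.8, and with Dox 14.96, 45.2 and 67.9, against 26.7. The mean r of Gli2 with Gli1, 0.0525 at 10000 UMIs, passed unthinned (0.127), at 20000 UMIs (0.0871) and unthinned given the UMI count (0.126), each with exact sign-flip p = 0.0312, was 0.0285 to 0.0650 without 1 library, and was 0.0279 with another random thinning (exact sign-flip p = 0.219). The excess variance of Gli1, 0.336 on average, was 0.228 to 0.901 under the alternatives with a value in each library. At 5000 UMIs and with at most 5% mitochondrial UMIs Experiment 1 at 30 h held too few Gli1 UMIs, so no mean was formed. At 5000 UMIs the excess was 0.605 in Experiment 1 at 17 h, 0.0078 and 0.219 in Experiment 2 at 19 and 30 h, and -0.087 and 0.317 with Dox. The r of Gli2 with Gli1 there was 0.047, 0.003, 0.034, 0.028 and 0.025 in the same order.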

Other observations

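Thinning of the libraries to the same total was set before the data were seen, but its use as a test of depth for Dox, and the test in cells lowest in cell cycle counts, were chosen only after the result was seen. Across the cells of the SAG-treated libraries, thinned to 10000 UMIs, Gli1 went with its co-target Ptch1 and with collagen genes. Of 7519 genes, Ptch1 had the highest median r with Gli1 over the 6 libraries, 0.118, followed by Col4a1 (0.117), Col6a1 (0.116), Col3a1 (0.113), Col4a2 (0.110), Fn1 (0.104), the glycosyltransferase gene Gxylt2 (0.104) and Eva1b (0.102), each above 0 in 6 of 6 libraries. The lowest were Ran, a nuclear transport GTPase (-0.130), and Ybx1, an RNA-binding protein (-0.125), both below 0 in 6 of 6, and Lgals1 (-0.115) and the serine synthesis gene Psat1 (-0.113), both below 0 in all but 1. In all, 476 genes were above 0 in all 6 libraries and 377 below, against 117.5 per direction by chance for independent genes.

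By list, the median r with Gli1 was 0.0552 for extracellular matrix genes, 24 of 28 above 0 and 18 of them in all 6 libraries, higher than in all 10000 random lists of genes of like mean. It was 0.0255 for the Hedgehog targets (percentile 99.91 of the random lists). It was -0.0437 for G2 to M genes, 24 of 26 below 0, with Mki67 and Cks2 among the lowest, -0.0416 for ATF4 genes, 21 of 24 below 0, with Psat1 and Asns, and -0.0318 for glycolysis genes such as Pkm and Gapdh. These 3 lists, the G1 to S genes (-0.0213) and the cholesterol synthesis genes (-0.0206) were lower than all random lists. The genes of a random list were drawn independently, while those of a real list can vary together. Medians of random lists therefore spread less, and the places among them can overstate the evidence.

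Barcodes with at least 5000 UMIs but over 10% mitochondrial UMIs, which were not kept, had more Gli1 and Ptch1 and less Mki67 than those of 1% to 10%. In Experiment 1 at 17 h Gli1 was at 13.87 against 8.766 CPM, Ptch1 at 39.51 against 23.46 and Mki67, a proliferation marker, at 15.02 against 24.75. In Experiment 2 at 30 h without Dox they were at 20.02 against 16.11, 81.43 against 55.8 and 4.289 against 19.88 CPM. Gli1 and Ptch1 were higher in 6 of 6 SAG-treated libraries and Mki67 lower in 9 of 9 libraries.

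The correlation of Gli1 with matrix genes and against ATF4 genes across cells may reflect the state of each cell, and a pair of technical or cell cycle explanations were tested. Position in the cell cycle is argued against only as far as the cell cycle counts of the cell capture it. The median r of the matrix list was 0.0519 given these counts, against 0.0552. Such counts are sparse in thinned cells, so the adjustment may be incomplete. Mitochondrial share and depth are argued against too, at 0.0503, and the ATF4 list went from -0.0416 to -0.0374 and -0.0321 in the same settings. Both tests used the libraries in which the pattern was found, and contact or density of the cells was not tested.

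Across the 3 SAG times 5233 genes were called with Dox. The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. Of the 10, 1 gave as many genes, the real split with 5233, and the highest of the others was 0. The other splits put both libraries of a SAG time on the same side, or swapped the arms at a single time. The latter moves the difference between the arms into the residual spread. A count of 0 there is a product of the design, and the splits cannot tell whether the grouping arose by accident. The total depth of the libraries is argued against, with 3997 genes called at the same total. That thinning cannot speak to depth per cell, which at 19 h was a median of 38969 UMIs with Dox and 8025 without. Cell cycle composition is argued against too, with 4164 called among the cells lowest in cell cycle counts, 3721 of them shared. Another difference between the cultures of the arms may have had the same effect and stays open, since the Dox difference at 0 h had r = 0.802 across genes with that at 30 h and each arm may come from a single culture. An effect of Dox, or of what it induces, stays open beside it.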
